A study of Mus musculus with 6 samples.

How the data were processed

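Single-cell RNA was measured in tumour tissue from mouse livers. Per the labels, Hepa1-6 cells, a mouse hepatoma line, either PGK1 wild type (WT) or PGK1 knockout (KO), were placed in 20 uL of Matrigel under the capsule of the left lateral liver lobe, and the tumours were taken 4 weeks later. Per the labels' protocols, the tissue was dissociated, red blood cells were lysed, cells were loaded on a Singleron microwell chip with barcoded beads, and the GEXSCOPE libraries were sequenced with 150 bp paired-end reads. Each group has 3 libraries, and all 6 libraries carry the same batch label. The labels do not say that the replicates are separate animals, so the edgeR and permutation p-values measure only the spread between these samples, which may be technical. The camera p-values at a preset correlation compare a list's genes with all other genes. They do not measure the spread between libraries. They also do not say how the knockout was made, so the second group is called KO-labelled throughout.

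The values are UMI counts per gene and barcode, as deposited by the authors, with no normalization. Per the submitters' processing notes, STARsolo and STAR 2.7.11a were used with the mouse builds GRCm38 and mm10, which name the same assembly. The annotation release and the treatment of reads that match more than 1 gene are not given in the sources used here, so members of near-identical families named here (H2-Q4, H2-Q6 and H2-Q7, Hspa1a, Serpina1a, Serpina3f and Serpina3g, Ces1c, Fth1, and Pgk1 with its processed pseudogenes) carry some uncertainty. Every deposited barcode holds at least 500 UMIs, so cells had been called before deposit. Of the 33989 gene identifiers in the files, 32292 matched the GENCODE M21 annotation of GRCm38, from which all gene positions are taken.

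Cells with at least 500 UMIs, at least 200 genes and at most 20% of UMIs from mitochondrial genes passed. Doublets were marked per library with Scrublet in scanpy 1.11.5 (expected rate 0.06) and removed. The automatic threshold marked 0 cells in KO-labelled replicates 2 and 3, where it lay at 0.722 and 0.650. There the median threshold of the other 4 libraries, 0.258, was used, a choice made after the automatic one had failed, which marked 288 and 273 cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes (without mitochondrial, ribosomal protein, haemoglobin genes, Pgk1 and Xist) gave 40 principal components, and a shared-neighbour graph of 20 neighbours was clustered with leidenalg 0.10.2 at resolution 1.0 into 28 clusters. No batch integration was applied. No cell annotation by the authors was used, so clusters were named from fixed markers of 23 cell classes, and a name required at least 3 detected markers. Such rebuilt names can differ from those of the study. Cluster 4 was left unnamed because more markers of cholangiocytes than of the tumour stood among its 10 leading genes, and cluster 5 because its cells held under 0.333 of their libraries' median UMI count with no tumour marker among those genes.

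Raw counts were summed per library over the cells of each class, because cells are not replicates, for the 8 classes with at least 20 cells in every library. Sums were compared between the groups with edgeR 4.0.16 (R 4.3.3) in its quasi-likelihood F test, with TMM scaling and filterByExpr, each class fitted alone, and Benjamini-Hochberg adjustment at 0.05. Log2 changes are KO-labelled over WT with standard errors. CPM relates a gene's count to the class sum. Fixed gene lists, 34 in all, were tested where at least 5 members were measured, with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists within a class. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. Shares of cells were compared with a two-sided exact permutation test over the 20 assignments of the libraries, and 3 against 3 cannot give a p below 0.1. The Pgk1 difference was also compared between the tumour-like class and each host class with an interaction term and the library as a block.

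Genes were named by a fixed rule. In the tumour-like class these are Pgk1 and 13 core genes of ferroptosis whatever their result, then the 10 largest rises and 10 largest falls among genes that passed, did not overlap between the groups and had a mean of at least 50 counts per library. In host classes the rule takes 5 and 5. From each list described, 2 to 4 members with the smallest p are added, and where no gene passed, the 3 genes with the smallest p are given as values. Unnamed gene models and immunoglobulin and T-cell receptor segments were passed over. Counts of named genes that passed are over all genes the rule picked, some of which the report does not describe. The groups, markers, gene lists, tests, naming rule and most alternatives were fixed before the data were examined. Which of the 34 lists are described for a class was decided after their results were seen.

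A gene is called free-RNA-prone in a class when another of the 8 tested classes held it at 3 times the level or more, since RNA released from other cells can then reach it. Fibroblast-like, Kupffer-like, plasmacytoid dendritic-like and unnamed cells were not counted as sources, so RNA from them can go unmarked by this measure. This measure, first tried with a ratio of 5, was chosen after the data were seen, as were the comparison of Xist and Ddx3y between clusters and the settings that set shares against named host cells alone, fit single clusters, add cluster 4 to the tumour-like class, leave out its shallow cluster 8 or leave out clusters 13 and 16, which have hepatocyte markers among their 20 leading genes.

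The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the replicate number as a block, doublets kept, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial UMIs), resolutions 0.5 and 2.0, and leaving out each library in turn. The tests were checked on simulated data with 200 changed genes. With the spread of the tumour-like class and 15258 genes, edgeR recovered 33.7% of genes changed by a log2 of 1 and 83.7% of those changed by 2, with 5% false calls, against 18.7% false calls for DESeq2. With the spread of macrophages and 12908 genes, edgeR recovered 82.5% and 96.9%, with 5.98% false calls, against 5.52% for DESeq2. The simulated noise was drawn for each gene independently, with no shift of a whole library. In the real tumour-like class edgeR called 0 genes with all 6 libraries and 2858 without KO-labelled replicate 1. These recoveries may therefore not hold there.

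Total UMIs per library ran from 91431765 to 114894835. Summed per class they ran from 37909720 to 73299483 in the tumour-like class, from 4901881 to 25535430 in T cells, from 161147 to 409836 in B cells and from 87150 to 403361 in endothelial cells, so the last 2 classes resolve fewer genes. Fibroblast-like, Kupffer-like and plasmacytoid dendritic-like cells were too few in at least 1 library to be tested for genes.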

Results

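Tumours grown from Hepa1-6 cells in mouse liver were profiled cell by cell to ask how they differ with and without PGK1, the glycolytic kinase that makes ATP from 1,3-bisphosphoglycerate, with ferroptosis, a form of cell death driven by lipid peroxidation, as the study's stated theme. There were 3 libraries of PGK1 WT tumours and 3 of tumours labelled PGK1 KO. The WT libraries held 107087468, 101730111 and 114894835 UMIs over 16702, 16315 and 16896 barcodes (replicates 1 to 3), and the KO-labelled libraries 107250206, 95130199 and 91431765 UMIs over 16145, 16660 and 17835 barcodes. After filtering, 15705, 15691 and 16195 WT cells and 15283, 16208 and 17359 KO-labelled cells remained. Median UMIs per kept cell were 4456, 2799 and 3667 in the WT libraries and 2744, 2154.5 and 2124 in the KO-labelled libraries, over different mixes of cell classes. No pair of replicates was a duplicate, since their counts differed by 63.0 to 417 times the sampling noise (chi-square per degree of freedom over genes). Values below are means of 3 libraries per group, with ± for the SD of CPM and shares and the standard error of log2 changes, and adjusted p-values are from edgeR unless a list is named, where they are from camera.

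Pgk1 transcript was present in all 6 libraries, and its mean was not lower in those labelled KO. KO-labelled replicate 1 alone lay below every WT library, in the tumour-like class and over all kept cells (921 CPM). In the tumour-like class Pgk1 (ENSMUSG00000062070, chromosome X, 106187100 to 106203699, GRCm38) stood at 791, 1010 and 739 CPM in WT replicates 1 to 3 and at 631, 2317 and 1370 CPM in KO-labelled replicates 1 to 3 (847 ± 144 against 1440 ± 845 CPM, n = 3 each). The log2 change was 0.81 ± 0.48 with an edgeR adjusted p of 0.515. Over all kept cells the means were 1182 ± 158 and 1317 ± 459 CPM. The labels do not say how the gene was disrupted, and counts from the 3' end of a transcript can stay where an edit ends the protein, so these values neither check nor contradict the labels, and every direction given here is that of the libraries as labelled.

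Pgk1 in host cells served as background, since these carry no edit. Mean Pgk1 levels were 836 and 906 CPM in T-cell-like cells (WT, then KO-labelled), 960 and 1193 in macrophage-like cells, 959 and 772 in neutrophil-like cells and 526 and 652 in dendritic-like cells. None of the 7 host classes passed the edgeR test for Pgk1, with log2 changes from -0.51 (endothelial-like) to 0.32 (macrophage-like). Within the tumour-like class the change rested on single libraries: it was 1.20 with an adjusted p of 0.0362 without KO-labelled replicate 1, and 0.22 without KO-labelled replicate 2. Cluster 1 held the largest part of the tumour-like cells of each WT library, clusters 1 and 10 most of those in KO-labelled replicate 1, and clusters 7, 8 and 10 most of those in KO-labelled replicates 2 and 3. The Pgk1 change was 0.70, 0.77 and 0.91 in clusters 8, 13 and 10 alone, -0.16 in cluster 7 alone, the opposite sign, and 0.01 in unnamed cluster 4. Levels differed between clusters: 2256 and 2125 CPM in cluster 7 (WT, then KO-labelled), 2727 and 2723 in cluster 4, 505 and 909 in cluster 10. Cluster 7 held 100550 of the 113011 Pgk1 counts of the class in KO-labelled replicate 2. In WT replicate 2 it held 20526 of 53637, the most of any WT library.

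**Figure D1:**
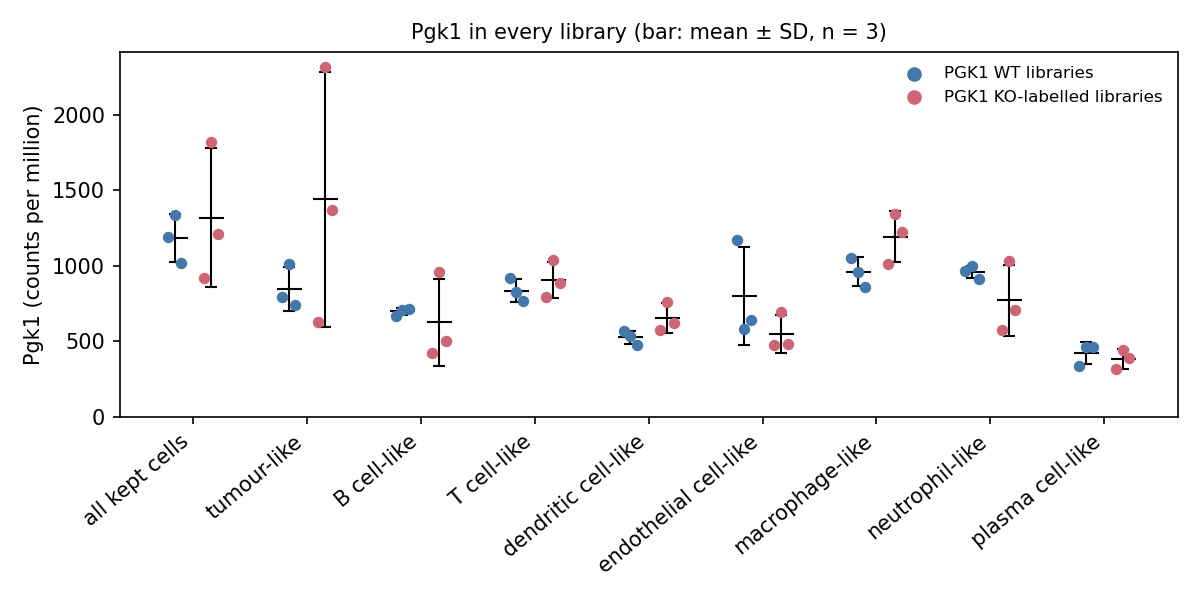
Pgk1 level (CPM of the class sum, vertical axis) in each library for all kept cells, the tumour-like class and the host classes, with WT and KO-labelled libraries as separate points and the group mean and SD marked. The KO-labelled tumour-like points run from 631 to 2317 CPM and the WT points from 739 to 1010 CPM.

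The tumour-like clusters could be told from host cells by a pair of sex-linked transcripts, looked at after the clusters were named. Xist, the RNA of the inactive X chromosome, ran from 40.5 to 587 CPM over the 7 tumour-like clusters and Ddx3y, a Y-linked gene, from 2.49 to 8.01 CPM. In the named host clusters Xist ran from 6.05 to 35.2 CPM and Ddx3y from 21.1 to 90.5 CPM. Both unnamed clusters lay with the tumour (Xist 83.5 and 104 CPM, Ddx3y 3.66 and 8.20 CPM in clusters 4 and 5), as did cluster 16, whose leading genes were those of mature liver such as Apoa2 and Fabp1 (44.5 and 3.84 CPM).

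T-cell-like cells made up more of the KO-labelled tumours and tumour-like and fibroblast-like cells less. The T-cell-like share was 16.8 ± 3.44% of kept cells in WT and 37.2 ± 10.0% in KO-labelled libraries. All 3 KO-labelled libraries (25.7, 42.6 and 43.4%) lay above all 3 WT libraries (16.5, 20.3 and 13.5%; exact permutation p = 0.1, the smallest that 3 against 3 allows, and 0.3 after Benjamini-Hochberg adjustment over 12 classes). Dendritic-like cells were at 1.17 ± 0.413% and 1.94 ± 0.112%, and fibroblast- or stellate-like cells, the makers of collagen, at 0.790 ± 0.220% and 0.0576 ± 0.00703% (exact p = 0.1 each). Tumour-like cells were at 35.0 ± 5.47% and 22.5 ± 7.07% (exact p = 0.2), or 26.8 ± 5.08% and 21.1 ± 6.23% without clusters 13 and 16 (exact p = 0.3). At resolutions 0.5 and 2.0 they were at 52.96 and 32.34%, and at 38.9 and 20.2% (exact p = 0.1 each). The unnamed cells were at 17.9 ± 2.62% and 9.74 ± 5.73%, of which cluster 4 held 11.4 ± 2.28% and 3.81 ± 3.19% and cluster 5 held 6.51 ± 1.18% and 5.94 ± 3.42%.

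For the other named classes the exact p ran from 0.2 to 0.9. Macrophage-like cells were at 8.99, 11.7 and 12.2% in the WT and 10.8, 14.6 and 14.1% in the KO-labelled libraries (a difference of 2.21 percentage points, exact p = 0.3). Neutrophil-like cells were at 14.2 ± 1.82% and 12.6 ± 3.90% (exact p = 0.7) and endothelial-like cells at 0.617 ± 0.320% and 0.253 ± 0.0556% (exact p = 0.2). B-cell-like cells were at 0.780 ± 0.358% and 0.983 ± 0.142% (exact p = 0.5) and plasma-like cells at 1.14 ± 0.595% and 1.07 ± 0.481% (exact p = 0.9). Plasmacytoid dendritic-like cells were at 0.355 ± 0.221% and 0.191 ± 0.0490% (exact p = 0.4) and Kupffer-like cells, the resident macrophages of the liver, at 0.270 ± 0.206% and 0.251 ± 0.113% (exact p = 0.8). Of the cells outside the tumour-like class, the unnamed included, T-cell-like cells made up 25.7 and 47.5% (exact p = 0.1), neutrophil-like cells 21.9 and 16.3% (0.1), dendritic-like cells, now with overlap, 1.78 and 2.52% (0.2) and macrophage-like cells 16.87 and 16.92% (1). Of the cells in named host classes alone they made up 35.7 and 54.4% (exact p = 0.1), 30.37 and 18.96% (0.1), 2.45 and 2.94% (0.4) and 23.3 and 19.5% (0.1), so the macrophage-like difference turned with the cells it was set against, as did that of B-cell-like cells (1.61 and 1.52%). The exact test cannot pass a threshold of 0.05 with 3 against 3, shares add up to a whole so that a larger class lowers the others, and all depend on how the tissue came apart. The stricter cell filter turned the neutrophil-like difference from -1.67 to 2.22 percentage points. Leaving out 1 library turned the sign for neutrophil-like cells (0.412 percentage points without KO-labelled replicate 3), plasma-like cells (0.273 without WT replicate 2, 0.177 without KO-labelled replicate 1) and Kupffer-like cells (0.0379 and 0.0443 without WT replicates 2 and 3, 0.0296 without KO-labelled replicate 3).

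**Figure D2:**
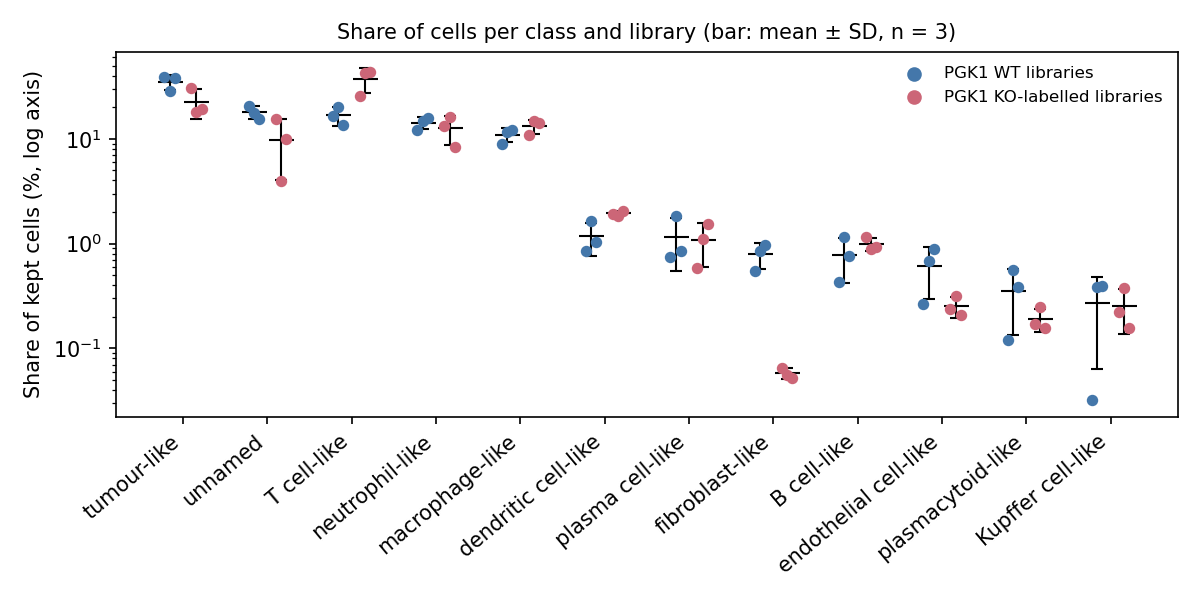
Share of kept cells (percent, vertical log axis) per library for each cell class, with points for the WT and KO-labelled libraries and the group mean and SD marked. The T-cell-like share was above 25% in each KO-labelled library and at most 20.3% in the WT libraries.

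Genes of ferroptosis in the tumour-like class did not move as a group. Slc7a11 (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614), the cystine importer that feeds glutathione synthesis, was at 17.1 ± 6.06 CPM in WT and 16.6 ± 5.29 CPM in KO-labelled libraries (log2 -0.01 ± 0.36, edgeR adjusted p = 0.988). Its partner chain Slc3a2 was at 132 ± 5.91 and 131 ± 18.7 CPM. Gpx4, the peroxidase that clears lipid peroxides, had a log2 change of 0.35 ± 0.12, Acsl4, which loads polyunsaturated fatty acids into lipids, 0.57 ± 0.16, Aifm2, a ubiquinone reductase, 0.25 ± 0.13, and Ptgs2, often used as a marker of ferroptosis, 1.24 ± 0.46 from 1.53 CPM. The iron genes Tfrc and Fth1 were at -0.84 ± 0.25 and -0.50 ± 0.28, and Hmox1, which frees iron from haem, at 0.74 ± 0.41. Nqo1, Gclc and Gclm, all targets of the oxidative stress factor NRF2, were at -1.28 ± 0.62, -0.47 ± 0.16 and -0.73 ± 0.27, and Chac1, which breaks down glutathione, at 0.84 ± 0.60. None of the 13 core genes passed (edgeR adjusted p from 0.364 to 0.988). In this fit edgeR called 0 of 15494 genes, against 2858 without KO-labelled replicate 1, so changes in these genes are not excluded. Slc7a11 stood 14.5 times higher in another class, and Hmox1, Chac1 and Ptgs2 12.9, 8.62 and 202 times. Genes at 3 times the level or more in another tested class, which RNA released from other cells can reach, are called free-RNA-prone here.

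Of the 21 measured members of the ferroptosis defence list 12 had positive and 9 negative log2 changes (median 0.05, mean -0.04, camera direction down, adjusted p = 0.691). Of the 17 of the ferroptosis promoting list 7 were positive (median -0.05, mean 0.05, camera direction down, adjusted p = 0.691). No member of either list passed, over all genes or adjusted over the list alone. The smallest p in these lists belonged to Slc40a1, the iron exporter (-0.86 ± 0.25), Txnrd1, thioredoxin reductase (0.31 ± 0.09), and Por, cytochrome P450 reductase (-0.48 ± 0.13). The direction of the promoting list turned to up without WT replicate 3 (adjusted p = 0.932) and without KO-labelled replicate 1 (0.684). NRF2 targets, such as Prdx1 at -0.43 ± 0.13, had a median of -0.10 (adjusted p = 0.0936), and passed without WT replicate 3 (0.00854).

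Interferon-response and antigen-presentation genes were higher in the tumour-like class of the KO-labelled libraries as lists, with no single gene past the test. With an estimated correlation the camera adjusted p of each of the 3 lists below was 0.631. All 22 measured members of the interferon gamma response list had positive changes (median log2 1.42, camera adjusted p = 1.41e-17), among them Gbp5 and Serpina3g (2.02 ± 0.24 and 1.94 ± 0.24, edgeR adjusted p = 0.232 each) and Socs1, a feedback inhibitor of cytokine signalling (1.60 ± 0.26). Of 27 type I interferon genes 26 were positive (median 0.96, adjusted p = 2.78e-10), for example Ifit2 at 1.89 ± 0.29 and Bst2 at 0.69 ± 0.14. Of 18 MHC class I presentation genes 16 were positive (median 0.96, 3.52e-08), for example B2m, the light chain of class I molecules (823 ± 170 to 1607 ± 278 CPM), and Tap1, the peptide transporter (1.14 ± 0.27). Adjusted over the list alone, 21, 12 and 15 members passed. In this class 16 of the 22 interferon gamma genes, 23 of the 27 type I genes and 8 of the 18 MHC class I genes were free-RNA-prone. The cytotoxicity list of T and NK cells, whose 16 measured members were all free-RNA-prone there, was also higher (median 1.93, camera adjusted p = 2.30e-09 and 0.635 with an estimated correlation).

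**Figure D3:**
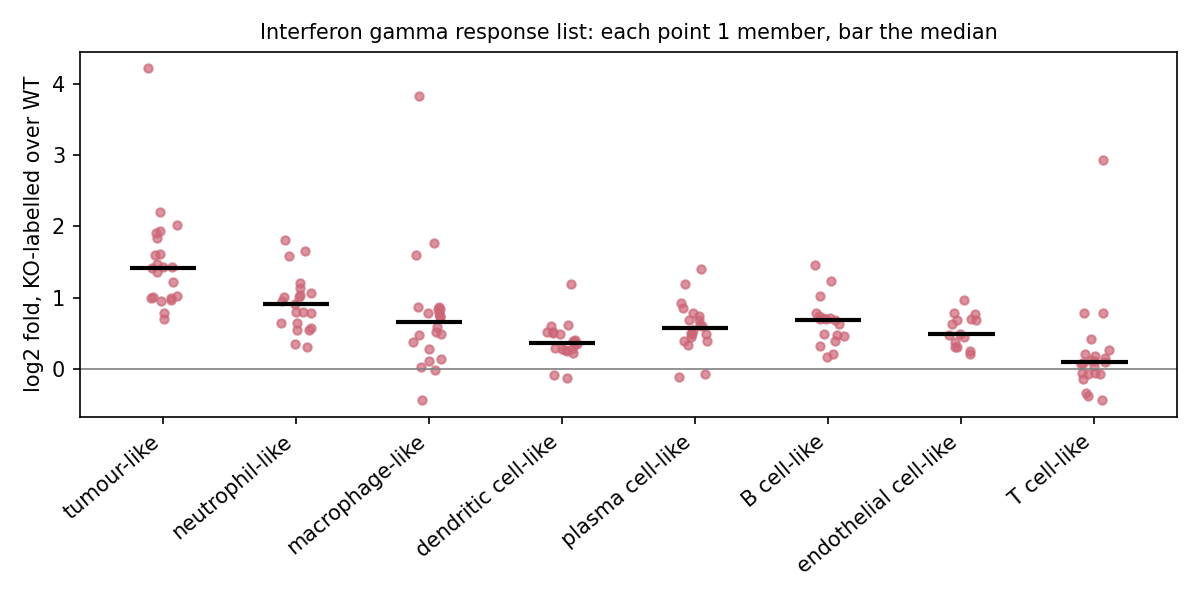
Log2 change (KO-labelled over WT, vertical axis) of the interferon gamma response genes in each cell class, with each member drawn as a point and the median as a bar. The tumour-like median lies at 1.42 and the neutrophil-like median at 0.91.

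Division and fatty acid oxidation genes were lower in the same class as lists, and hypoxia and glycolysis genes higher. With an estimated correlation the camera adjusted p was 0.631 for fatty acid oxidation and 0.635 for the other 3 lists. Of 48 G2/M phase genes 46 were negative (median -0.33, camera adjusted p = 8.18e-07), such as Cdc20 at -0.70 ± 0.30. All 15 fatty acid oxidation genes were negative (median -0.35, 6.01e-07), such as Acaa2 at -0.69 ± 0.16 and Etfdh at -0.46 ± 0.10. All 17 hypoxia genes were positive (median 0.63, adjusted p = 0.00272), such as Vegfa, the endothelial growth factor (0.87 ± 0.43), and Car9 (1.21 ± 0.38). So were 16 of 18 glycolysis genes (median 0.28, 0.0235), such as Pfkl and Pfkp (0.40 ± 0.13 and 1.04 ± 0.40). No member passed over all genes, and adjusted over the list alone only 3, of fatty acid oxidation, did. Hypoxia lost its call without KO-labelled replicate 2 (0.128), and glycolysis without WT replicate 3 (0.0864), KO-labelled replicate 2 (0.128) or KO-labelled replicate 3 (0.0814) and without clusters 13 and 16 (0.124). Unnamed cluster 4, which lay with the tumour by Xist and Ddx3y, is not in this class. It made up 11.4% of kept WT cells and 3.81% of kept KO-labelled cells. Its Pgk1 level was 2727 and 2723 CPM (WT, then KO-labelled), against 847 and 1440 CPM in the class. At resolution 2.0 an unnamed cluster with Vegfa among its leading genes held 1261, 977 and 885 WT and 772, 112 and 166 KO-labelled cells. Leaving these cells out may have raised the hypoxia and glycolysis lists.

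edgeR called 0 of 15494 genes in the tumour-like class, where 1795 had an unadjusted p under 0.05 and DESeq2 called 482 (318 higher, 164 lower). The smallest p values belonged to Sp140, a nuclear body protein of immune cells (1.31 ± 0.14, free-RNA-prone), and the transporters Slco1b2 (-3.32 ± 0.35) and Slc16a12 (-2.22 ± 0.23), each with an adjusted p of 0.232. Groups did not overlap for 2455 genes (15.8%, against 10% by chance). Without KO-labelled replicate 1, edgeR called 2858 genes (1688 higher, 1170 lower), and 0 without any other single library (736 to 1638 at an unadjusted p under 0.05).

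T-cell-like cells of the KO-labelled libraries held more of the cytokine transcripts Csf2 and Lta and less of the cytotoxic genes Eomes and Gzma. Csf2 (ENSMUSG00000018916, chromosome 11, 54247271 to 54249667), which encodes GM-CSF, rose from 18.7 ± 0.157 to 54.7 ± 12.1 CPM (log2 1.56 ± 0.17, edgeR adjusted p = 0.00585) and Lta, lymphotoxin alpha, by 1.55 ± 0.13. Lgals7, a galectin, rose by 2.03 ± 0.20, AA467197 by 1.71 ± 0.17 and Ifitm1 by 1.62 ± 0.30, the last 2 free-RNA-prone. Of the 18 cytotoxicity genes measured 3 rose and 2 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.902). Tbx21, the type 1 lineage factor, rose by 0.45 ± 0.06 and Gzmc by 1.44 ± 0.30, while Eomes (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132), a related factor, fell by 1.73 ± 0.17 and the granzyme Gzma by 1.59 ± 0.22. The mix of T-cell-like clusters differed as well: of kept cells, cluster 0, with Cd4 and Icos among its leading genes, made up 6.49% in WT and 17.4% in KO-labelled libraries, cluster 9, led by Setbp1 and Themis, with a median of 1087 UMIs and 4.36% mitochondrial UMIs per cell against 2255 and 1.94% in cluster 0, 1.25% and 6.82%, cluster 3, led by Prf1 and Cd8b1, 6.45% and 9.88%, and cluster 21, led by Foxp3, 1.01% and 0.476%. In cluster 3 alone Eomes and Gzma changed by -1.33 and -1.49 (edgeR adjusted p = 0.00177 and 0.0146) and Csf2 by 0.65 (0.431). Eomes and Gzma are also NK-cell markers, and with a separate NK-like class at resolution 2.0 their changes in T-cell-like cells were -1.71 and -1.64. The Gzma call was lost without WT replicate 2 (edgeR adjusted p = 0.0508) or KO-labelled replicate 3 (0.0666), and in cluster 0 alone Gzma had the opposite sign (0.34).

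Of 14 exhaustion genes only Havcr2, which encodes TIM-3, passed (0.63 ± 0.10, edgeR adjusted p = 0.022; 1 rose and 2 fell adjusted over the list alone). Cd160 and Tox had changes of -0.39 ± 0.10 and -0.38 ± 0.15, and the list did not stand apart (camera adjusted p = 0.841). Glycolysis genes were slightly higher as a list (median 0.12, camera adjusted p = 0.0381, and 0.804 with an estimated correlation), with 0 of 18 past the test over all genes or over the list alone and Hk2 at 0.33 ± 0.08. Of 19 NRF2 targets 4 fell, Ephx1 by 1.32 ± 0.22, Me1, Gsta4 and Prdx1 (1 rose and 7 fell adjusted over the list alone; median -0.21, adjusted p = 0.00335, and 0.699 with an estimated correlation), and 13 of the 19 were free-RNA-prone. The glycolysis call was lost without WT replicate 2 (0.103), WT replicate 3 (0.114) or KO-labelled replicate 2 (0.176), and also with the replicate number as a block. Cytotoxicity and exhaustion, which were not called, turned up in direction without WT replicate 1 (0.706 and 0.608) and without KO-labelled replicate 1 (0.811 and 0.987).

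Of 12991 genes tested in T-cell-like cells edgeR called 389 (177 higher, 212 lower), of which 182 were free-RNA-prone. The 5 largest falls were all of that kind: the liver genes Apoa2 (74.9 ± 63.0 to 4.36 ± 1.19 CPM), Fabp1, Ces1c and Itih3, with log2 changes of -4.13, -3.15, -2.98 and -2.89, and Lcn2 (-2.69). Without free-RNA-prone genes 207 were called (137 higher, 70 lower). The count was 146, 22 and 59 without WT replicates 1, 2 and 3, and 1873, 140 and 39 without KO-labelled replicates 1, 2 and 3. Of the 19 named genes that passed, 13, 4, 10, 19, 12 and 6 passed again with those libraries left out in that order.

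Macrophage-like cells showed the most called genes of the 8 classes by edgeR, and the interferon gamma response, MHC class I and pro-inflammatory lists were higher by camera, though not with an estimated correlation (adjusted p = 0.746 each). Of the 22 interferon gamma response genes 14 rose and 0 fell (17 and 1 adjusted over the list alone; median 0.66, camera adjusted p = 8.45e-07). Socs1 (ENSMUSG00000038037, chromosome 16, 10782240 to 10785536) rose from 61.2 ± 4.03 to 208 ± 22.3 CPM (1.77 ± 0.13, edgeR adjusted p = 0.00304), the chemokine Cxcl10 by 0.84 ± 0.08 and the transcription factor Irf1 by 0.79 ± 0.10. Of 18 MHC class I genes 8 rose (11 adjusted over the list alone; median 0.28, 6.27e-04), including H2-Q6 (1.10 ± 0.13), Tap2 (0.71 ± 0.11) and Nlrc5, the activator of class I genes (0.87 ± 0.15). Of 16 pro-inflammatory genes 9 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.85, 0.00116), including Ptgs2, cyclooxygenase 2 (1.65 ± 0.21), Cd80, a costimulatory molecule (0.86 ± 0.12), and Ccl5 (1.63 ± 0.24). Irf1, H2-Q6, Ptgs2, Cd80 and Ccl5 were free-RNA-prone in this class.

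Of 18 glycolysis genes 5 rose in macrophage-like cells (9 adjusted over the list alone; median 0.25, camera adjusted p = 0.00380, and 0.754 with an estimated correlation), including the hexokinases Hk2 (0.70 ± 0.11) and Hk1 (0.58 ± 0.11), Aldoc (1.14 ± 0.16) and the lactate exporter Slc16a3 (0.82 ± 0.18). Of 48 G2/M phase genes 46 were negative and 0 passed over all genes or over the list alone (median -0.43, adjusted p = 8.82e-05, and 0.754 with an estimated correlation), with Nuf2 at -0.88 ± 0.32, and 33 of the 48 were free-RNA-prone.

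The largest rises were of Inhba, a subunit of activin (5.61 ± 5.75 to 67.9 ± 43.1 CPM, 3.75 ± 0.79), Tnfrsf9, which encodes 4-1BB (3.26 ± 0.65), Slc4a11 (2.95 ± 0.31), Rab44 (2.73 ± 0.36) and the cystatin Cst7 (2.60 ± 0.33). The largest falls were of Itgad, an integrin chain (27.7 ± 14.6 to 0.654 ± 0.366 CPM, -5.35 ± 0.56), Fgfr1 (-4.84 ± 1.08), Slco2b1 (-4.52 ± 0.49), Cbr2 (-4.13 ± 1.02) and Fcna, a ficolin of resident macrophages (243 ± 109 to 14.3 ± 6.58 CPM, -4.06 ± 0.42, edgeR adjusted p = 0.004). Tnfrsf9, Rab44, Cst7 and Fgfr1 were free-RNA-prone. Cluster 11, led by the complement genes C1qa and C1qc, held the largest part of the class in WT (4.74 ± 0.643% of kept cells against 1.89 ± 0.298%) and cluster 6, led by Lyz2, with monocyte markers such as Ly6c2 and Ccr2 beside macrophage ones, in KO-labelled libraries (3.24 ± 0.609% against 8.71 ± 1.43%). Fitted alone they gave 466 and 341 called genes. Cluster 22, with Marco and Fcna among its leading genes, was at 0.915 ± 0.710% and 0.0205 ± 0.0143%. In all, edgeR called 1745 of 13072 genes (987 higher, 758 lower). The count was 903, 1017 and 338 without WT replicates 1, 2 and 3, and 3427, 712 and 232 without KO-labelled replicates 1, 2 and 3. Of 25 named genes that passed 24, 20, 17, 25, 19 and 13 passed again in that order.

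Neutrophil-like cells carried the same 2 interferon-related lists at higher levels by camera, though with an estimated correlation the adjusted p of these and of the 2 other lists below was 0.347. Their mix also differed: at resolution 2.0 cluster 9, with a median of 831 UMIs per cell, held 861, 846 and 966 WT and 486, 156 and 80 KO-labelled cells, and cluster 8 (1160 UMIs) 242, 371 and 548 against 747, 1049 and 697. Of 21 interferon gamma response genes 11 rose (19 adjusted over the list alone; median 0.91, camera adjusted p = 1.35e-12), including Cd274, which encodes PD-L1 (871 ± 13.9 to 1713 ± 150 CPM, 1.01 ± 0.12, edgeR adjusted p = 0.0118), Socs1 (1.14 ± 0.13) and Irgm1 (1.04 ± 0.14). Of 18 MHC class I genes 10 rose (16 adjusted over the list alone; median 0.63, 1.57e-08), including H2-Q7 (1.13 ± 0.19) and H2-Q4 (0.69 ± 0.12). Of 15 genes of the pro-inflammatory list 6 rose (8 adjusted over the list alone; median 0.61, 1.93e-04), including the cytokines Il1a (1.78 ± 0.25) and Tnf (0.69 ± 0.11). Of 14 fatty acid oxidation genes 3 fell (4 adjusted over the list alone; median -0.39, 0.00980), including Acaa2 by 1.03 ± 0.20 and Ppara by 1.78 ± 0.42. H2-Q7 and Acaa2 were free-RNA-prone. The last list lost its call without KO-labelled replicate 1 (0.0564).

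The largest rise in neutrophil-like cells was that of the chemokine Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453; 20.5 CPM in WT and 121 CPM in KO-labelled libraries, 2.61 ± 0.24, edgeR adjusted p = 0.00492). The next 4, Ifng, Cxcr6, Thy1 and Ms4a4b (2.46, 2.39, 2.36 and 2.09), are T-cell genes, and the 4 largest falls, Ces1c (-3.60), Apoa2 (-3.54), Fabp1 (-2.81) and Ces2e (-2.07), are liver genes, all 8 free-RNA-prone. edgeR called 426 of 10633 genes (283 higher, 143 lower), of which 160 were free-RNA-prone. The count was 11, 3 and 6 without WT replicates 1, 2 and 3, and 2354, 127 and 0 without KO-labelled replicates 1, 2 and 3. The 0 was edgeR's, with 1636 genes at an unadjusted p under 0.05 and no other tool run there, while of 23 named genes that passed 4, 2, 3, 23, 11 and 0 passed again in that order.

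Dendritic-like cells held more Socs1, and their dissociation stress list was lower by camera. Socs1 rose from 74.7 ± 4.74 to 173 ± 7.61 CPM (1.19 ± 0.13, edgeR adjusted p = 0.00134), the only one of 20 interferon gamma response genes past the test (10 adjusted over the list alone; median 0.36, camera adjusted p = 3.50e-07, and 0.352 with an estimated correlation). Of 18 MHC class I genes 17 were positive with 0 past the test (9 adjusted over the list alone; median 0.26, 1.21e-05, and 0.191 with an estimated correlation), Tap2 among them at 0.45 ± 0.10. The dissociation stress list, genes that tissue handling induces, was lower (2 of 20 fell, 12 adjusted over the list alone; median -0.58, 2.47e-08, and 0.316 with an estimated correlation): Hspa1a fell by 1.38 ± 0.18 and Egr1 by 0.74 ± 0.13. The other largest rises were of Upp1, uridine phosphorylase (2.39 ± 0.26), Ccl24 (1.77 ± 0.33), Ccl17, a chemokine for CCR4 (1.73 ± 0.24), Selenom (1.60 ± 0.32) and Lyz2 (1.44 ± 0.25). The other falls were of the histone H2bc4 (-1.55 ± 0.22), Serpinf2 (-1.43 ± 0.26), Clu (-1.27 ± 0.24) and Hp (-1.23 ± 0.19). Upp1, Ccl24, Selenom, Lyz2, Serpinf2, Clu, Hp and Egr1 were free-RNA-prone. Ccl17 was among the fixed markers of migratory dendritic cells, and the mix of dendritic-like cells was not held fixed. At resolution 2.0 cluster 35, led by Ccl22 and Ccr7, held 27, 61 and 34 WT and 72, 107 and 123 KO-labelled cells. Cluster 30, led by Wdfy4, held 106, 195 and 132 against 224, 191 and 234. edgeR called 61 of 9642 genes (39 higher, 22 lower), or 402 (227 higher, 175 lower) with the replicate number as a block, against 32, 20 and 29 without WT replicates 1, 2 and 3, and 333, 63 and 17 without KO-labelled replicates 1, 2 and 3. Of 12 named genes that passed 7, 5, 6, 12, 10 and 5 passed again.

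In plasma-like cells the MHC class I and interferon gamma response lists were higher by camera, though not with an estimated correlation (adjusted p = 0.308 each). Txndc5, a disulfide isomerase of the endoplasmic reticulum, rose from 357 ± 25.8 to 1011 ± 172 CPM (1.55 ± 0.15, edgeR adjusted p = 2.83e-04). Itgb7, an integrin chain, rose by 2.50 ± 0.31, Ifi27l2a by 2.09 ± 0.21 and Serpina3f by 2.07 ± 0.39, and a gene with no symbol in the files, ENSMUSG00000121501, by 2.15 ± 0.27 (the last 4 free-RNA-prone). Of 18 MHC class I genes 2 rose, Tapbp by 0.90 ± 0.15 and H2-T23 by 0.77 ± 0.16 (7 adjusted over the list alone; median 0.36, camera adjusted p = 7.96e-06). Of 20 interferon gamma response genes 1 rose (6 adjusted over the list alone; median 0.58, 1.01e-05, 19 of 20 free-RNA-prone). The largest falls, Serpina1a (-2.99), Lcn2 (-2.44), Kng1 (-1.69), Clu (-1.54) and Aldh2 (-1.32), were all free-RNA-prone. edgeR called 97 of 7695 genes (55 higher, 42 lower), 63 of them free-RNA-prone. The balance turned with the replicate number as a block (90 higher, 112 lower) and with doublets kept (83 higher, 112 lower). The count was 41 and 37 without WT replicates 1 and 3, and 23 and 51 without KO-labelled replicates 2 and 3. Of 13 named genes that passed, 7, 12 and 5 passed again without WT replicates 1, 2 and 3, and 7, 5 and 4 without KO-labelled replicates 1, 2 and 3.

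In endothelial-like cells 7 of 2673 genes rose and 0 fell by edgeR (459 at an unadjusted p under 0.05, 42 by DESeq2, 30 higher and 12 lower), among them Ptprb, the vascular receptor phosphatase (ENSMUSG00000020154, chromosome 10, 116275523 to 116389535; 469 ± 132 to 1561 ± 412 CPM, 1.72 ± 0.28, adjusted p = 0.0482). With the replicate number as a block edgeR called 86 genes (63 higher, 23 lower), and with no filter on low counts 224 (108 higher, 116 lower). All 17 type I interferon genes were positive, 0 of them past the test (2 adjusted over the list alone; median 0.72, camera adjusted p = 5.43e-06), with Ifit3 at 1.57 ± 0.34. Of 10 genes of angiogenic endothelium 8 were negative with 0 past the test (5 adjusted over the list alone; median -0.72, 0.00994), with the basement membrane collagen Col4a1 at -0.73 ± 0.23 and the VEGF receptor Flt1 at -0.96 ± 0.28. Both lists had an adjusted p of 0.365 with an estimated correlation. The 7 calls became 0 without WT replicate 1 or 2 or KO-labelled replicate 2 or 3, 1 without WT replicate 3 and 134 without KO-labelled replicate 1, all by edgeR (340 to 462 at an unadjusted p under 0.05 where 0 were called), and Ptprb passed again only in the last.

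In B-cell-like cells edgeR called 0 of 5672 genes (496 at an unadjusted p under 0.05), 87 with no filter on low counts and 103 (30 higher, 73 lower) with the replicate number as a block. DESeq2 called 3, Lcn2, Ifng and Lck, which had edgeR changes of -2.43 ± 0.38, 3.44 ± 0.56 and 2.50 ± 0.43 with an adjusted p of 0.0831 each and were all free-RNA-prone. All 18 interferon gamma response genes were positive with 0 past the test (9 adjusted over the list alone; median 0.69, camera adjusted p = 1.31e-08), with Irf1 at 0.70 ± 0.19. Of 18 MHC class I genes 16 were positive, 0 of them past the test (1 adjusted over the list alone; median 0.36, 9.50e-04), with B2m at 0.39 ± 0.14. Both had an adjusted p of 0.317 with an estimated correlation. edgeR called 2 and 5 genes without WT replicates 1 and 2, 8 and 1 without KO-labelled replicates 1 and 2, and 0 without WT replicate 3 or KO-labelled replicate 3 (397 and 301 at an unadjusted p under 0.05).

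Secreted liver proteins, the hepatic secretory list, were lower in all 8 classes by camera. The median log2 change was -0.38 in the tumour-like class (adjusted p = 3.91e-04, and 0.549 without clusters 13 and 16), where 0 of 20 passed (1 adjusted over the list alone). In host classes it was -1.26 in T-cell-like (6 fell, 13 adjusted over the list alone), -0.75 in macrophage-like (4 and 7), -1.29 in neutrophil-like (5 and 15), -0.89 in dendritic-like (2 and 5), -1.25 in plasma-like (3 and 16), -0.97 in endothelial-like (0 and 2) and -1.09 in B-cell-like cells (0 and 10). The adjusted p with an estimated correlation ran from 0.299 to 0.746. All measured members were free-RNA-prone in every host class except the neutrophil-like, where 18 of 20 were.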

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

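No test in this part was added after the results were seen. The Pgk1 difference between the groups was larger in the tumour-like class than in 4 host classes, by an interaction term with the library as a block. The tumour-like minus host difference in log2 change was 0.90 against B-cell-like cells (edgeR adjusted p = 0.00450), 1.26 against endothelial-like cells (0.000171), 0.97 against neutrophil-like cells (0.00450) and 0.76 against plasma-like cells (0.00411). Against T-cell-like, dendritic-like and macrophage-like cells it was 0.46, 0.32 and 0.36 (adjusted p = 0.310, 0.315 and 0.315). These p-values are adjusted over the host classes, Pgk1 being the only gene asked about. Adjusted over all genes tested, the first 4 were 0.441, 0.00433, 0.143 and 0.0572 in that order. Without the library as a block the first 4 differences were 1.01, 1.47, 1.13 and 0.94 and did not pass (0.171 each). The direction is that of the libraries as labelled, and the Pgk1 change within the tumour-like class rested on single libraries. The mix of tumour clusters may carry part of it. Cluster 7, already at 2256 CPM in WT, held 100550 of the 113011 Pgk1 counts of KO-labelled replicate 2 and changed by -0.16 alone. Clusters 8, 10 and 13 alone changed by 0.70, 0.91 and 0.77.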

How the results depend on the processing

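Settings that fit single clusters, set shares against named host cells, add or leave out clusters of the tumour-like class or leave out free-RNA-prone genes were chosen after the data were seen, and the ratio of 3 after the named genes' values under a ratio of 5 were known. Of 3104 values of named genes under the alternatives 2553 kept their direction and side of the threshold, 324 no longer passed, 194 passed only there, 32 moved and 1 reversed. Of 288 values of the described lists 224 did, 57 no longer passed, 6 moved and 1 passed only there. Of 164 differences in share 9 changed sign, and only edgeR on cell counts could pass there, so the threshold says nothing of the others. The tumour-like difference was -12.4 points, -20.6 and -18.7 at resolutions 0.5 and 2.0 and -19.2 with doublets kept. As shares of cells outside that class the macrophage-like difference went from 2.21 to 0.0568 and the neutrophil-like from -1.67 to -5.61 points, and of named host cells to -3.79 and -11.4, with the B-cell-like at -0.0906. The cause of the changes was not tested except where a setting leaves out genes or libraries. Pgk1 in the tumour-like class ran from 0.22 to 1.20 with 1 library left out and was -0.16 in cluster 7 alone, with edgeR adjusted p from 0.0362 to 0.985 over all alternatives. Gzma in cluster 0 alone was 0.34.

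DESeq2 called 3 genes in B-cell-like, 482 in tumour-like, 702 in T-cell-like, 105 in dendritic-like, 42 in endothelial-like and 642 in neutrophil-like cells. With doublets kept the counts were 1 (B), 137 (T), 93 (dendritic), 1 (endothelial), 1090 (macrophage), 224 (neutrophil) and 195 (plasma). With no filter on low counts they were 87 (B), 1410 (T), 528 (dendritic), 224 (endothelial), 1643 (neutrophil) and 469 (plasma). Without free-RNA-prone genes they were 207 (T), 31 (dendritic), 266 (neutrophil) and 34 (plasma), and with a ratio of 5, 259 (T), 37 (dendritic) and 52 (plasma). The strict cell filter gave 0 in endothelial-like cells by edgeR (383 at an unadjusted p under 0.05; DESeq2 was not run there). Single clusters gave 177, 25, 189, 36 and 220 (clusters 4, 7, 8, 10 and 13), 136, 430 and 43 in T-cell-like clusters 0, 3 and 9, 341 and 466 in macrophage-like clusters 6 and 11, and 707 and 143 in neutrophil-like clusters 2 and 12. With 1 library left out the counts ran from 0 to 8 (B), 0 to 2858 (tumour), 22 to 1873 (T), 17 to 333 (dendritic), 0 to 134 (endothelial), 232 to 3427 (macrophage), 0 to 2354 (neutrophil) and 23 to 86 (plasma).

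The replicate block gave 103 genes in B-cell-like, 402 in dendritic-like, 86 in endothelial-like and 202 in plasma-like cells, a Pgk1 change of 0.61 and an adjusted p of 0.0702 for glycolysis in T-cell-like cells. The numbers were not taken as pairs, since over all kept cells and in every class but the dendritic-like at least 1 pair's correlation was below 0.1 (lowest -0.108 over all kept cells, 0.0163 in the tumour-like class). Both values belong to pair 3. Pairs 1 and 2 stood at 0.646 and 0.616 in the tumour-like class and at 0.563 and 0.586 over all kept cells, so a pairing of some libraries stays open. In dendritic-like cells all 3 were above 0.1 (0.164, 0.165 and 0.157). Of 6 libraries 6 correlated best with their own number in dendritic-like and in plasma-like cells, 5 in the tumour-like class and 4 over all kept cells.

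Camera with an estimated correlation called 0 lists in each of the 8 classes. Fry called 0 for B-cell-like, tumour-like, endothelial-like and macrophage-like, 2 for T-cell-like, 2 for dendritic-like, 5 for plasma-like and 7 for neutrophil-like cells. With 1 library left out the counts of lists ran from 7 to 12 (B), 15 to 19 (tumour), 6 to 9 (T), 6 to 11 (dendritic), 4 to 10 (endothelial), 11 to 16 (macrophage), 8 to 13 (neutrophil) and 8 to 14 (plasma). edgeR on cell counts passed for the shares of T-cell-like cells (log2 1.15) and fibroblast-like cells (-3.76), and the strict filter turned the neutrophil-like difference to 2.22 points. With 1 library left out the differences in share ran from 0.0297 to 0.387 (B), -16.5 to -10.1 (tumour), -0.137 to 0.0443 (Kupffer, above 0 at 0.0379, 0.0443 and 0.0296), 17.4 to 26.3 (T), 0.606 to 1.002 (dendritic), -0.539 to -0.225 (endothelial), -0.854 to -0.640 (fibroblast), 1.22 to 3.41 (macrophage), -3.45 to 0.412 (neutrophil), -0.304 to 0.273 (plasma, above 0 at 0.273 and 0.177), -0.281 to -0.0611 (plasmacytoid) and -11.0 to -5.29 points (unnamed). The Pgk1 interaction without the library block was 1.01 (B), 1.47 (endothelial), 1.13 (neutrophil) and 0.94 (plasma). Depth limits the smaller classes most, with 2673 genes tested in endothelial-like and 5672 in B-cell-like cells against 15494 in the tumour-like class.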

Other observations

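The tests with plasma-like cells left out, of Ifng over all cells, of the mix of tumour clusters and of other splits of the libraries were chosen after the results were seen, as were the lists in the next paragraph. The position of KO-labelled replicate 1 was added after the other results, with its bound set before the positions were seen. 

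The dissociation stress list, lower in dendritic-like cells, was also lower in plasma-like cells, where 7 of 20 members fell (10 adjusted over the list alone; median -0.57, camera adjusted p = 4.58e-06, and 0.308 with an estimated correlation), and in B-cell-like cells, where 0 of 19 passed (9 adjusted over the list alone; median -0.49, 3.95e-06, and 0.317 with an estimated correlation). In macrophage-like cells the oxidative phosphorylation list was higher, with 5 of 41 past the test (11 adjusted over the list alone; median 0.21, 0.00298, and 0.746 with an estimated correlation), and so was the hypoxia list, with 4 of 17 (6 adjusted over the list alone; median 0.50, 0.0285, and 0.754 with an estimated correlation). In T-cell-like cells 4 of 5 genes of extracellular matrix and fibroblasts fell (5 adjusted over the list alone; median -2.42, 3.53e-05, and 0.699 with an estimated correlation), beside the smaller share of fibroblast-like cells.

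The interferon gamma response list was higher in 7 of the 8 classes by camera, and in 0 with an estimated correlation. In the tumour-like, neutrophil-like and macrophage-like classes, argued against is that different clusters held a class in the groups as the whole cause. Of 12 clusters fitted alone 11 had a median above 0 (mean 0.873, standard error 0.205, from -0.10 to 2.09). The 12 include unnamed cluster 4 (2.09) and T-cell-like clusters, where the list was not called. All share the same 6 libraries, so this standard error does not measure the spread between libraries. The mix may carry part in macrophage-like cells (0.66, and 0.27 and 0.46 in clusters 6 and 11 alone). The mix may carry part in the tumour-like class too, where clusters 7, 8, 10 and 13 alone gave 1.59, 1.13, 0.43 and 1.52. The largest WT cluster of that class, cluster 1, was not fitted. Neutrophil-like clusters 2 and 12 alone gave 1.01 and 1.60. A finer mix within them, which differed at resolution 2.0, was not tested. The dendritic-like, plasma-like, B-cell-like and endothelial-like classes are each a single cluster, within which a finer mix was not tested. In 6 classes argued against, as the source of the whole level, is free RNA of tumour cells (host classes) or T cells (tumour-like class). There the list's share of its level over all cells was at least 3.74 times that of genes the class should lack (up to 12.7). Free RNA stays open in plasma-like cells (2.58), so over all 7 called classes the test as first set could not decide. Only levels in KO-labelled libraries were compared, against tumour markers in host classes and T-cell markers in the tumour-like class. Free RNA of immune cells was not bounded in host classes. The list's share was 3.24, 1.70, 1.49 and 1.40 in neutrophil-like, macrophage-like, dendritic-like and endothelial-like cells, and 0.860 in the tumour-like class. Whether free RNA carries part of the change between the groups thus stays open in all these classes. In B-cell-like cells the shares were 0.862 for the list and 0.231 for genes the class should lack. More interferon gamma from T cells may be behind the list's rise: Ifng was at 31.3 ± 8.93 CPM over all WT cells and 162 ± 99.7 CPM over KO-labelled cells (exact permutation p = 0.1), but both the T-cell-like share and Ifng within T-cell-like cells (568, 487 and 447 CPM in WT, 596, 648 and 847 in KO-labelled libraries) go with the groups, so these cannot be told apart. An effect of the PGK1 edit itself stays open as untested.

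The hepatic secretory list was lower in the host classes by camera, and not with an estimated correlation. The median change of 7 of 7 host classes lay within 1 SD over genes of the change over all kept cells (-0.76). This met the bound set beforehand for tumour RNA carried as free RNA. That window is too wide to decide, and all 7 medians lay below the change over all kept cells (-0.77 to -1.36). By this further rule, which was not part of the bound, the explanation was left open. The macrophage-like median was a near tie (-0.77). These changes are log2 ratios of mean CPM, so their medians differ slightly from the edgeR medians given above. A lower expression of these genes within host cells was not tested.

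With 1 library left out, edgeR called genes in the tumour-like class only without KO-labelled replicate 1 (2858), while DESeq2 called 482 with all 6 libraries. A wrong label on that library stays open: its profile lay nearer to the WT libraries in 5 of 8 classes, with near ties on that side in B-cell-like (distances of 0.599 to WT and 0.608) and T-cell-like cells (0.373 and 0.380) and on the other in macrophage-like (0.461 and 0.443) and dendritic-like cells (0.484 and 0.467). On genes called without it, from 0 at the WT mean to 1 at the other KO-labelled libraries, it lay at 0.412, 0.487, 0.532 and 0.854 in T-cell-like, dendritic-like, macrophage-like and plasma-like cells, above the highest held-out WT library (0.298, 0.330, 0.252 and 0.398) and by over 2 SD in 1 of 4 (plasma-like), and in classes with too few genes for that comparison at 0.00811 (tumour), 0.344 (neutrophil), 0.364 (endothelial) and -0.000855 (B). Its shares of fibroblast-like cells (0.0654%), cluster 6 (7.14%) and cluster 9 (6.13%), picked after they were seen, lay with the other KO-labelled libraries and outside the WT ranges (0.548 to 0.976%, 2.60 to 3.82% and 0.902 to 1.68%). A different mix of tumour clusters is consistent with the result, since 5 of 5 tumour clusters fitted alone called genes (25 to 220), but 1 of these is unnamed cluster 4, only 4 of the 7 clusters of the class were fitted, not the largest (cluster 1), and whether the tumours differ in biology was not tested.

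The 6 libraries make 10 splits, too few for a share under 0.05. The real split and the highest other gave 0 and 1 genes in B-cell-like cells (10 splits gave as many as the real one), 0 and 0 in tumour-like (10), 389 and 0 in T-cell-like (1), 61 and 3 in dendritic-like (1), 7 and 0 in endothelial-like (1), 1745 and 0 in macrophage-like (1), 426 and 0 in neutrophil-like (1) and 97 and 1 in plasma-like cells (1). All these counts of genes are edgeR's. Every other split holds libraries of both groups on each side, so a difference between the groups widens the spread there and lowers these counts. Low counts in the other splits thus do not measure what chance would give. For lists they gave 9 and 14 (3 splits), 17 and 18 (3), 8 and 13 (5), 8 and 9 (2), 6 and 7 (2), 13 and 16 (4), 10 and 13 (6) and 14 and 9 (1) in the same order.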
